A study of Homo sapiens with 4 samples.

How the data were processed

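RNA was measured in RKO cells, an established human colon carcinoma line, in 2 libraries: 1 from cells overexpressing HADH-S and 1 from control cells labelled wild type. HADH encodes a mitochondrial hydroxyacyl-CoA dehydrogenase of fatty acid beta-oxidation, and the series title describes a nuclear isoform of it. Per the labels' protocols, total RNA was isolated with Trizol and submitted to mRNA library construction. The series also holds a chromatin immunoprecipitation library for HADH-S and an input library from overexpressing cells; both were not analysed here.

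The authors deposited 1 table per RNA library with 1 RPKM value per gene (reads per kilobase of transcript, scaled to the size of the library), per the file headers. Each row is labelled with a gene symbol, an Ensembl gene and transcript identifier, the bounds of the coding sequence and a transcript length, although the header calls it a RefSeq identifier. Per the submitters' processing notes, which are shared by all samples of the series, fastp 0.23.2, SAMtools 1.9, MACS2 1.4.2, ChIPseeker and the GRCh38 build were used. The RNA aligner, the read counter, the strand setting and the annotation version are not given in the sources used here.

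Each RPKM value multiplied by the row's transcript length was a whole multiple of a single step per library. In both libraries 100% of values came out whole within a tolerance of 0.01 reads, with a largest deviation of 3.6e-05 reads. The recovered reads added up to 6963608 for HADH-S and 6773421 for the control, which equalled the totals implied by the steps, so the library size used in RPKM is the number of reads assigned to the listed genes. Genes without a read are not listed. A gene listed in 1 table and missing from the other was therefore taken as having 0 reads there, and a gene missing from both was not evaluated, since it may not have been in the authors' annotation. The symbols of 12799 of the 13092 genes equalled those that the reference name table gives for their identifiers, and 13073 identifiers were found in it. By RefSeq biotype, matched through the Ensembl identifier or the symbol, 97.0% of rows were protein-coding. Coordinates were taken from the RefSeq annotation of GRCh38.p14.

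With 1 library per condition no test between conditions exists, and no p-value is given. The comparison used log2((RPKM + 1) with HADH-S / (RPKM + 1) in the control), with a pseudocount of 1, among the 10331 genes with a mean RPKM of at least 1 over both libraries. On this scale the change of low genes is understated. A gene was counted as higher or lower when this value reached 1 or -1, a rule of size and not of significance. Ratios of RPKM carry an exact conditional (Clopper-Pearson) 95% interval from the recovered reads. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. "Higher" and "lower" therefore describe these 2 libraries.

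Before the data were examined, 34 gene lists were fixed, covering lipid and energy metabolism, cell cycle, signalling and stress responses, interferon response, antigen presentation, markers of other cell types, and signs of RNA quality. Members were matched by symbol or, failing that, by the identifier that the reference name table gives for it. For each list with at least 5 members at a mean RPKM of at least 1, the median log2 value was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, which describes these libraries and is not a p-value. With 29 such lists, 1.45 would stand apart by chance if the members of a list varied independently of each other. Genes of a list can move together between 2 cultures, so more may stand apart without an effect of HADH-S. The genes named were also fixed beforehand: HADH, the 15 protein-coding genes with the largest increase and the 15 with the largest decrease at a mean RPKM of at least 1, and the 3 members of each list with the largest absolute change. Of the lists that did not stand apart, only part of these members are described, and some genes are not reported here. Genes outside this rule are introduced as chosen after their values were seen.

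The steps were tested on simulated reads drawn for the 10331 genes from the mean levels of the 2 libraries. Of genes changed by 1.5 on the log2 scale, 92% passed the rule of size, and of genes changed by 3, 100% did. The true ratio lay within 95.6% of the counting intervals. Of 200 unchanged lists of 25 genes, 5.5% stood apart, and 100% of lists shifted by 0.2 on the log2 scale did. These simulations hold counting error only.

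Alternatives were pseudocounts of 0.1, 0.5 and 5, rescaling to equal RPKM totals, to a median log2 value of 0 and to equal 75th percentiles, no filter and a mean RPKM of at least 5, a fold of 1.5, protein-coding genes only, list means, 10 expression bins, and removal of a trend with transcript length (lowess, span 0.3). A minimum of 50 reads over both libraries, and the removal of the length trend for HADH and the gene counts, were added after the data had been seen. A check of GC content needs transcript sequences and was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.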

Results

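To find genes that respond to HADH-S in colorectal cancer cells, the study sequenced RNA from RKO cells overexpressing HADH-S and from control RKO cells, with 1 library for each. RKO is a poorly differentiated human colon carcinoma line. The library of overexpressing cells held 6963608 reads assigned to 12612 genes, with a median of 206 reads per listed gene. The control library held 6773421 reads over 12501 genes, with a median of 200. Both tables listed 12021 genes in common, 591 were listed only with HADH-S and 480 only in the control. The highest RPKM among the genes listed in a single table was 2.30 with HADH-S and 1.503 in the control. At the median transcript length, 3 reads corresponded to 0.137 RPKM with HADH-S and 0.141 RPKM in the control. There were no replicates, so no difference below has a replicate check. The separate chromatin immunoprecipitation of HADH-S and its input were not analysed here.

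HADH itself was examined first, since it checks the labels. HADH (ENSG00000138796, on chromosome 4 from 107989889 to 108035171 in GRCh38.p14) was at 54.4 RPKM in the library labelled HADH-S overexpression and at 26.5 RPKM in the control, from 651 and 309 reads. The ratio was 2.05, with a 95% counting interval of 1.79 to 2.35, and the log2 value was 1.01. The direction was that of the label. HADH lay at the edge of the rule of size used below, and its log2 value was 0.98 when both libraries were rescaled to equal RPKM totals. The reads were assigned to a single transcript of 1719 nt (ENST00000505878), so the values sum whatever isoforms share it and do not separate HADH-S from the full-length form. The 2 subunits of the mitochondrial trifunctional protein, which act in the same pathway and were chosen after their values were seen, had ratios close to 1. HADHA was at 101 RPKM against 111 in the control (ratio 0.912, interval 0.859 to 0.968) and HADHB at 76.2 against 77.8 (ratio 0.979, interval 0.898 to 1.07).

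The 2 transcriptomes were close to each other apart from a small set of genes that were mostly higher with HADH-S. Of the 10331 genes with a mean RPKM of at least 1, 31 were higher by the rule of size and 5 were lower. Interferon-stimulated genes made up 12 of the 31, although only 36 of the 10331 genes were on that list. Counting error alone would place 1.37 genes above and 1.30 below these limits. With a minimum of 50 reads over both libraries, a requirement added after the data had been seen, 18 genes were higher, 10 of them on the interferon list, and 0 were lower. The median log2 value over the 10331 genes was 0.01, 95% of them lay between -0.36 and 0.49, and Pearson's r of log2(RPKM + 1) across genes was 0.992. Genes are not independent replicates. Across genes, the log2 ratios spread 1.71 times as widely as counting error predicts, so the counting intervals given here are narrower than the full difference between 2 libraries warrants.

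**Figure D1:**
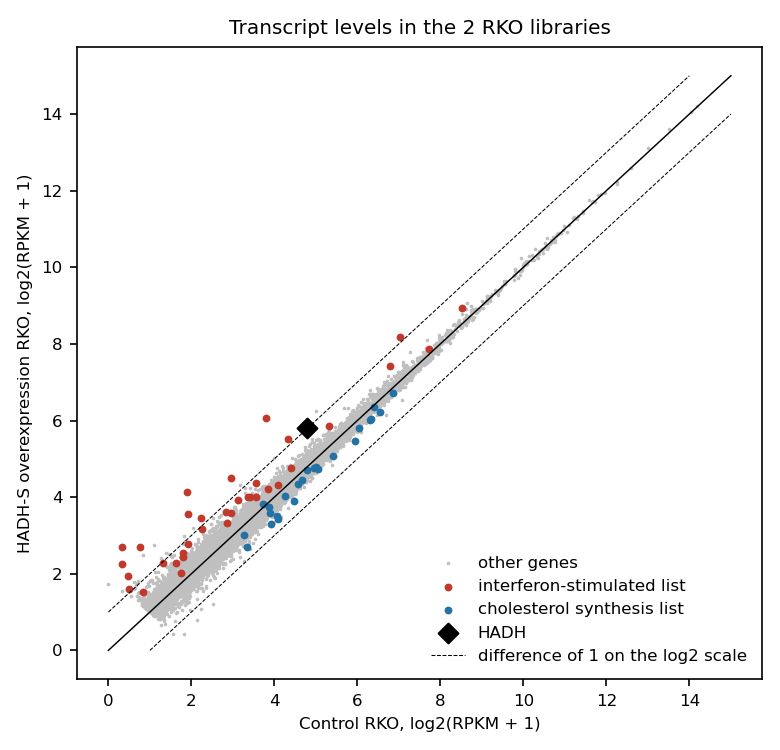
Transcript levels of the 10331 genes with a mean RPKM of at least 1, as log2(RPKM + 1), in control RKO cells (horizontal axis) and in RKO cells overexpressing HADH-S (vertical axis), 1 point per gene and 1 library per axis. The solid line marks equality and the dashed lines a difference of 1 on the log2 scale; HADH (black diamond) lies at 1.01 above equality, the 36 interferon-stimulated genes (red) all lie above it, and 23 of the 24 cholesterol synthesis genes (blue) lie below it.

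Interferon-stimulated genes were the group that differed most. All 36 measured members were higher with HADH-S, 27 of them by at least 1.5-fold and 12 by at least 2-fold on the log2(RPKM + 1) scale, and the list's median log2 value was 0.79, a 1.72-fold difference. OAS1, which makes the 2'-5' oligoadenylates that activate RNase L, was at 5.54 RPKM with HADH-S and at 0.263 RPKM in the control. That ratio of 21.1 rests on 65 reads against 3 and has a counting interval of 6.90 to 105. IFI6, an interferon-induced membrane protein, stood at 66.4 RPKM against 12.9 (ratio 5.13, interval 3.98 to 6.70). IFIT1, which binds viral RNA lacking cap methylation, stood at 16.7 RPKM against 2.75 (ratio 6.08, interval 4.79 to 7.80). The antiviral enzyme RSAD2 (viperin) had a ratio of 7.90 (4.69 to 14.2), and the antiviral GTPases MX1 and MX2 had ratios of 2.38 (2.13 to 2.66) and 7.24 (3.60 to 16.5). IFI44 differed by a ratio of 14.3 (4.57 to 71.8), from 44 reads against 3, IFITM1 by 3.89 (2.22 to 7.21) and IFIT3 by 2.71 (2.01 to 3.69).

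IRF9 and STAT2, of the transcription factor ISGF3 that carries the type I interferon signal to the nucleus, were higher as well. IRF9 was at 21.5 RPKM against 6.72 (ratio 3.19, interval 2.45 to 4.20). STAT2, chosen after its values were seen, was at 8.998 against 6.27 RPKM. The counting interval lay above 1 for 35 of the 36 members and included 1 for the remaining one, IRF1. The list's median exceeded those of all 10000 matched random lists, 95% of which lay between -0.06 and 0.09. IFIT, IFITM, MX and OAS genes have close paralogs, and IFIT1, IFIT3 and RSAD2 overlap other coding genes, so the division of reads among them is uncertain.

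**Figure D2:**
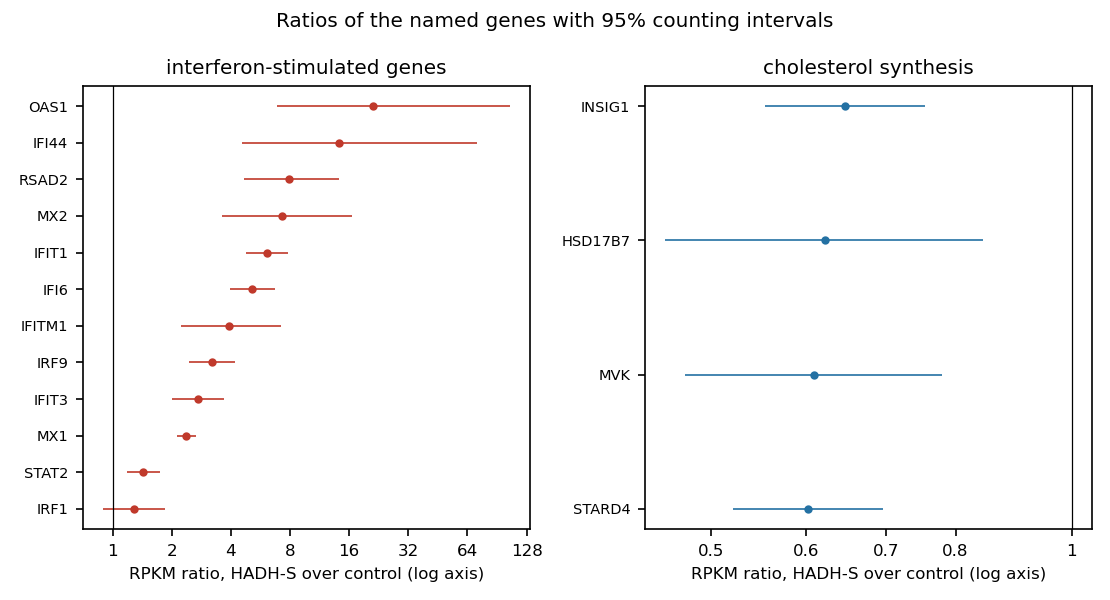
RPKM ratios of HADH-S over control on a log axis for the interferon-stimulated genes (left) and the cholesterol synthesis genes (right) that the text names, not the whole lists; points are ratios of 1 library to 1 library and bars are 95% counting intervals, which contain no replicate spread. The interferon-stimulated genes shown extend from IRF1, whose interval includes 1, to 21.1 for OAS1, and the cholesterol synthesis genes shown extend down to 0.603 for STARD4.

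Genes of MHC class I antigen presentation were higher with HADH-S by smaller factors. Of 17 measured members, 15 had a positive log2 value, 10 had a counting interval above 1, 0 had one below 1, and the median log2 value was 0.26, a 1.20-fold difference. HLA-B, a classical class I heavy chain, was at 26.0 RPKM against 17.6 (ratio 1.48, interval 1.22 to 1.79). PSMB9, a catalytic subunit of the immunoproteasome, was at 23.9 against 16.5 RPKM (ratio 1.44, interval 1.13 to 1.85), and HLA-E at 48.3 against 36.6 RPKM (ratio 1.32, interval 1.19 to 1.47). The list's median exceeded the central 95% range of matched random lists, -0.08 to 0.10. Reads of the near-identical HLA genes cannot be assigned with certainty.

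Genes of cholesterol synthesis and uptake were lower with HADH-S as a group, each by less than 2-fold. Of the 24 members, 23 had a negative log2 value, 17 had a counting interval below 1 and 0 had one above 1, with a median log2 value of -0.27, a factor of 0.830. STARD4, a sterol carrier, was at 9.71 RPKM with HADH-S and 16.1 RPKM in the control (ratio 0.603, interval 0.522 to 0.696). MVK, the mevalonate kinase, was at 5.53 against 9.07 RPKM (ratio 0.609, interval 0.475 to 0.779), and HSD17B7, a ketosteroid reductase of the same pathway, at 8.81 against 14.1 RPKM (ratio 0.623, interval 0.458 to 0.843). INSIG1, a sterol-dependent regulator of the pathway chosen after its values were seen, was at 13.8 against 21.4 RPKM. The list's median lay below those of all 10000 matched random lists, 95% of which lay between -0.07 and 0.09.

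The list of fatty acid synthesis did not stand apart (10 members, median -0.04, percentile 24.9). Within it, the stearoyl-CoA desaturase SCD was at 70.0 RPKM against 102 (ratio 0.686, interval 0.652 to 0.722), the elongase ELOVL6 had a ratio of 0.826 (0.765 to 0.893) and SCD5 one of 0.846 (0.724 to 0.987). Of the 10 members, these were the 3 with a counting interval below 1, and the 1 with an interval above 1 was the fatty acid synthase FASN (ratio 1.17, interval 1.10 to 1.26), chosen after its values were seen. Fatty acid beta-oxidation, the pathway of HADH, did not stand apart either. Its 25 members without HADH had a median of 0.00, 5 with a counting interval above 1 and 4 with one below. The isomerase ECI1 was at 36.2 RPKM against 25.6 (ratio 1.42, interval 1.21 to 1.66), the acyl-CoA synthetase ACSL3 at 24.0 against 31.3 (ratio 0.765, interval 0.702 to 0.835), and CPT1C at 1.18 against 1.88 (ratio 0.631, interval 0.361 to 1.08).

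A further 3 lists stood apart by small medians. Targets of p53 were higher, with 23 of 28 members above 0, a median log2 value of 0.11 and percentile 99.3. GDF15, a stress-induced cytokine, had a ratio of 1.79 (1.26 to 2.57), the BH3-only protein gene PMAIP1 one of 1.45 (1.07 to 1.98) and GADD45B one of 1.47 (0.931 to 2.36). Counting intervals lay above 1 for 8 of the 28 and below 1 for 0, and without a filter on low values the list was at percentile 96.1, within the range. Genes of G2 and mitosis were lower, with 20 of 29 members below 0, a median of -0.07 and percentile 1.05. Counting intervals lay below 1 for 10 of the 29 and above 1 for 1. The kinesin KIF20A had a ratio of 0.797 (0.685 to 0.928), the kinetochore protein gene CENPF one of 0.841 (0.799 to 0.885), and HMMR one of 1.38 (0.919 to 2.09). Genes of invasion and matrix remodelling were lower in 13 of 17 members, with a median of -0.10 and percentile 1.13, while counting intervals lay below 1 for 5 and above 1 for 4. Its members with the largest differences went both ways, since the protease inhibitor gene TIMP1 had a ratio of 1.34 (1.26 to 1.42), the matrix protease gene MMP14 one of 1.34 (1.07 to 1.68) and the integrin gene ITGAV one of 0.779 (0.697 to 0.870). After a trend with transcript length was removed, the invasion list was at percentile 11.2, and by its mean at 4.39, both within the range.

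**Figure D3:**
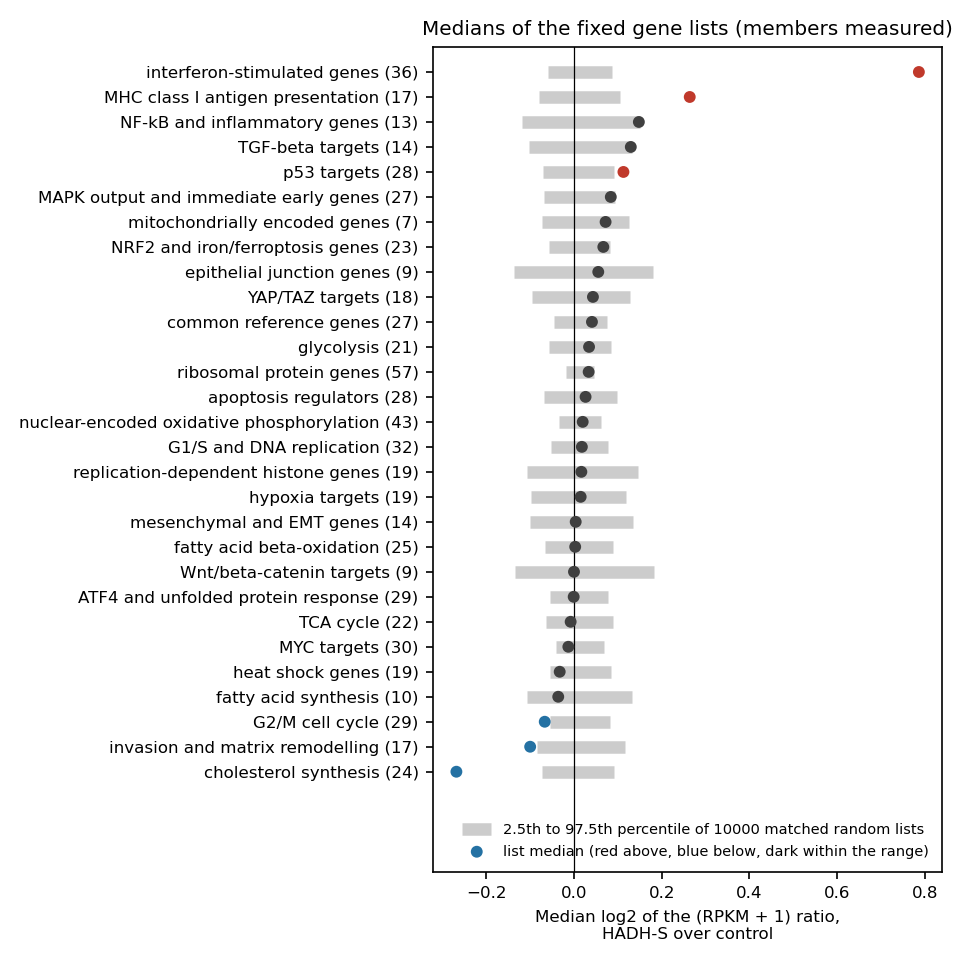
Median log2 value of each fixed gene list with at least 5 measured members (points; the number of members in brackets), with the central 95% range of 10000 random lists matched on expression (grey bars), HADH-S over control, 1 library each. The lists for interferon-stimulated genes (0.79) and MHC class I (0.26) lie far above their ranges and cholesterol synthesis (-0.27) far below; 23 lists lie within.

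The remaining lists with at least 5 measured members did not stand apart. Closest to the upper limit were NF-kB and inflammatory genes (median 0.15, percentile 97.3), TGF-beta targets (0.13, percentile 97.3), MAPK output and immediate early genes (0.08, percentile 95.9), and NRF2 and iron genes (0.07, percentile 93.7). Among them, the NF-kB inhibitor NFKBIA had a ratio of 1.46 (1.16 to 1.83), NFKB2 of 1.28 (1.08 to 1.52) and TNFAIP2 of 1.30 (1.04 to 1.61). Of the 13 NF-kB members, 3 had a counting interval above 1 and 2 had one below. Of the 14 TGF-beta members, 4 had one above 1 and 3 had one below. The differentiation inhibitor ID1, on the TGF-beta list, was at 31.6 RPKM against 14.9 (ratio 2.12, interval 1.67 to 2.72), its relative ID3 at 44.9 against 28.9 (ratio 1.55, interval 1.29 to 1.88), and ID2 at 1.76 against 0.868 (ratio 2.03, interval 0.981 to 4.43). HMOX1, the inducible heme oxygenase, was at 74.9 RPKM against 31.3 (ratio 2.40, interval 2.11 to 2.73). Also on the NRF2 list, the ferritin heavy chain FTH1 had a ratio of 1.27 (1.17 to 1.37). Among MAPK list members with a mean RPKM of at least 1, KLF2 (1.55, interval 1.09 to 2.22), ZFP36 (1.61, interval 1.02 to 2.58) and FOS (1.49, interval 0.947 to 2.36) had the largest ratios.

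In energy metabolism, the medians were 0.03 for glycolysis, -0.01 for the tricarboxylic acid cycle, 0.02 for nuclear-encoded oxidative phosphorylation and 0.07 for the 7 mitochondrially encoded genes listed. OGDH, a subunit of the oxoglutarate dehydrogenase complex, had a ratio of 1.38 (1.18 to 1.62) and the complex I subunit NDUFS7 one of 1.32 (1.10 to 1.59). The medians were 0.02 for G1/S and DNA replication, -0.01 for MYC targets, 0.00 for Wnt targets, 0.06 for epithelial junction genes, 0.00 for mesenchymal genes, 0.04 for YAP/TAZ targets, 0.02 for hypoxia targets and 0.00 for ATF4 and unfolded protein response genes. Median and mean differed in sign for beta-oxidation (mean -0.01), the tricarboxylic acid cycle (0.01), MYC targets (0.02), mesenchymal genes (0.00) and ATF4 targets (0.01), all close to 0. On the Wnt list, the pathway transcription factors TCF7L2 and LEF1 had ratios of 1.71 (1.21 to 2.44) and 0.821 (0.673 to 1.00). On the mesenchymal list, the actin-binding caldesmon CALD1 had one of 0.593 (0.518 to 0.679), TGFB1 one of 1.38 (1.23 to 1.55) and MSN one of 1.48 (1.09 to 2.03). The YAP partner TEAD1 had one of 0.644 (0.549 to 0.755), on a list whose log2 values reached 0.61 in the other direction. The medians were -0.03 for heat shock genes, 0.03 for apoptosis regulators, 0.03 for the 57 ribosomal protein genes, 0.02 for replication-dependent histone genes and 0.04 for genes in common use as references. The anti-apoptotic BCL2 had a ratio of 0.575 (0.416 to 0.788) and the death receptor gene TNFRSF10A one of 1.32 (1.15 to 1.51).

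Among the 15 protein-coding genes with the largest increases, 10 were on the interferon list. The other 5 were HMOX1, the sterol-sensing nuclear receptor NR1H3 (ratio 7.46, interval 2.25 to 38.8, from 23 reads against 3, in a gene that overlaps ACP2), IFI27L1 (ratio 5.06, interval 1.91 to 16.9) and the histone genes H4C1 and H4C11. H4C1 had 5 reads against 0, with a counting interval that starts at a ratio of 0.891 and so includes 1, and H4C11 had 12 against 2 (ratio 5.84, interval 1.30 to 53.7). The H4 genes are near-identical copies, so their counts are uncertain. The 15 largest decreases were mostly at low levels, with CALD1 the best covered at 352 against 577 reads, and of these genes only CALD1 (mesenchymal list) and H3C1 (histone list) were on a fixed list. The largest were H3C1 with 1 read against 7 (ratio 0.139, interval 0.00308 to 1.08), the Rab GTPase RAB4B with 6 against 27 (ratio 0.216, interval 0.0730 to 0.534), the cardiac troponin gene TNNI3 with 8 against 28 (ratio 0.278, interval 0.109 to 0.626), REP15 with 9 against 29 (ratio 0.302, interval 0.126 to 0.655) and RND1 with 4 against 22 (ratio 0.177, interval 0.0443 to 0.521). The others were BEX5, SPATA24, ACTR3C, UFSP1, BBIP1, HOXA4, GEMIN8, PVRIG and NUDT6, with log2 values from -0.94 for BEX5 to -0.71 for NUDT6.

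Markers of other cell types and signs of RNA quality were examined beside these groups. Of the fibroblast markers 0 reached a mean RPKM of 1. The endothelial list had 1 such member, EGFL7 (58.6 against 48.6 RPKM), and the leukocyte list had 3, namely CD68 (478 against 389 RPKM, ratio 1.23, interval 1.18 to 1.28), LCP1 (222 against 249, ratio 0.892, interval 0.861 to 0.924) and CORO1A (6.85 against 7.45, ratio 0.919, interval 0.677 to 1.25). The colonocyte differentiation list also had 3, CA2 (14.3 against 11.1 RPKM), CDX2 (4.37 against 3.60) and SLC26A2 (8.15 against 9.13). The non-coding and nuclear RNAs chosen as signs of RNA quality were not listed in either table. The listed mitochondrial transcripts held 5.41% of reads with HADH-S and 5.32% in the control, and the 10 most abundant genes held 9.07% and 9.06%.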

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

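Neither leaving out a replicate nor a paired analysis was possible with 1 library per condition. HADH stayed between 0.91 and 1.03 on the log2 scale under its 7 alternatives. It was below the size limit of 1 with a pseudocount of 5 (0.913) and without the length trend (0.964). Each rescaling also left it below 1, at 0.984 with equal totals, 0.997 with the median set to 0 and 0.993 with equal 75th percentiles. The gene counts followed the pseudocount and the treatment of low genes. The number of higher genes moved from 31 to 69 with a pseudocount of 0.1, to 8 with 5, to 12 at a mean RPKM of at least 5, to 152 at a fold of 1.5, and to 18 with at least 50 reads. The number of lower genes moved from 5 to 15 with a pseudocount of 0.1, to 8 with 0.5, to 9 without a filter, to 45 at a fold of 1.5, and to 0 with a pseudocount of 5, with a mean RPKM of at least 5 and with at least 50 reads. A larger pseudocount shrinks the values of low genes by construction, and the last 2 settings remove such genes. Rescaling the libraries left 30 higher and 5 lower genes each time and the median of all genes, 0.01 as deposited, was lowest at -0.01 with equal totals. Interferon-stimulated genes (medians 0.51 to 0.91, mean 0.96), MHC class I (medians 0.20 to 0.28, mean 0.23), cholesterol synthesis (medians -0.29 to -0.23, mean -0.30) and G2/M (medians -0.10 to -0.05, mean -0.06) stood apart under all 12 alternatives run for each. The invasion list came within the range by its mean (-0.055) and after removal of the length trend (-0.067), a trend taken up below. The p53 list came within the range without a filter (0.084), with 29 members instead of 28. The added member was SPATA18, with 4 reads against 3, and it lowered the list's median from 0.113 to 0.084. The upper limit of the random lists with the filter was 0.092. Adding 1 gene of few reads was therefore enough to bring the p53 median below that limit. Lists that came to stand apart were MAPK output (0.076 without the length trend), NF-kB (0.20 with a pseudocount of 0.1, 0.13 without a filter and 0.15 with at least 50 reads), NRF2 and iron genes (0.13 by the mean, 0.056 without the length trend) and TGF-beta targets (0.18 by the mean, 0.13 with 10 bins). The other 267 of 275 values of lists within the range stayed there, and 0 results reversed. Among them, the TGF-beta list moved away from the limit without a filter (0.041, percentile 76.6) and with at least 50 reads (0.084, percentile 88.7). The Wnt list had too few members at a mean RPKM of at least 5. Depth limits the low genes, where a change of a few reads passes the rule of size.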

Other observations

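The tests of counting error, of the construct, of single cultures and of unlisted leukocyte markers below were chosen after the results were seen; those of transcript length, of the ratio of leukocyte markers and of LXR targets were set before their own results were seen. All genes in the next sentences were picked after their values were seen. Beyond the fixed lists, further genes known to respond to interferon were higher with HADH-S: HELZ2 (8.14 against 3.08 RPKM, ratio 2.65, interval 2.21 to 3.18), DTX3L (ratio 1.62, interval 1.40 to 1.89) and TRIM25, a ubiquitin ligase of the RIG-I pathway (ratio 1.42, interval 1.27 to 1.58). Of the interferon genes looked up (IFNB1, IFNA1, IFNL1, IFNL2 and IFNL3), only IFNB1 was listed, with 2 reads with HADH-S and 0 in the control. The others were not evaluated, and further interferon genes were not looked up. The chemokine CCL5 had 7 reads against 2. Ferritin light chain FTL was higher by a ratio of 1.14 (1.12 to 1.17), beside HMOX1 and FTH1. Among genes of lipid metabolism outside the cholesterol list, LPIN1, a phosphatidate phosphatase, was lower (27.6 against 41.2 RPKM, ratio 0.669, interval 0.602 to 0.744), as was IDH1, a cytosolic source of NADPH (ratio 0.763, interval 0.698 to 0.835). The autophagy gene MAP1LC3C was at 91.1 against 133 RPKM (ratio 0.686, interval 0.625 to 0.753), and FAM102A at 17.9 against 9.62 (ratio 1.86, interval 1.62 to 2.15).

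For the higher interferon-stimulated genes, counting error as the only source was argued against by 35 of 36 members with an interval above 1 and 0 with one below. A trend with transcript length was argued against by a median that stayed at the 100th percentile once the trend was removed. The listed leukocyte markers under 1 RPKM had 26 reads against 27, a summed ratio of 0.937 whose interval (0.525 to 1.67) was too wide to separate it from the interferon list's 1.62 (1.58 to 1.66). Leukocyte RNA as the source of the whole difference is argued against by the 21 of 28 markers that were not listed in either table while the interferon list had 7120 extra reads with HADH-S, although CD68, also expressed in the control, was higher (ratio 1.23, interval 1.18 to 1.28) and LCP1 lower (0.892, interval 0.861 to 0.924). A single unlisted gene may be missing from the annotation. On all fixed lists other than the 4 of markers of other or differentiated cell types, 96 of 804 genes were unlisted. That allows a share of up to 14.4% (exact 95% limit), or 4.03 of the 28 markers. The limit treats gaps as independent and may be too low, since they were uneven across lists. Of the 13 mitochondrially encoded genes 6 were unlisted, while all 57 ribosomal protein genes were listed. A response to the introduced construct rather than to HADH-S cannot be told apart from an effect of HADH-S. The reason is that 0 RNA libraries are labelled as carrying a construct without it. With 1 library per condition, a difference between 2 single cultures cannot be told apart from such an effect either. Both limits apply to the other lists and genes described here as well. An effect of HADH-S on interferon signalling stays an untested hypothesis.

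The cholesterol synthesis genes were lower as a group. Counting error as the only source was argued against by 17 of 24 members with an interval below 1 and 0 with one above. Such intervals also occurred on lists that did not stand apart, since ratios spread 1.71 times as widely as counting error predicts. The ATF4 and unfolded protein response list had 9 of 29 members below 1 and 4 above. A trend with transcript length was argued against by a median that stayed at the 0th percentile once the trend was removed. A candidate explanation was a higher sterol content that lowers SREBP2 output and raises LXR targets. The 6 measured of 13 LXR targets had a median of 0.01 (percentile 47.4, with matched random lists from -0.19 to 0.25). The rule set beforehand counted a median no higher than the middle of the random lists against this explanation, and the median met it. The test was still read as undecided, which that rule did not provide for, since the members went both ways, from -0.53 to 0.16. MYLIP was lower (ratio 0.625, interval 0.448 to 0.867), and the intervals of the other members included 1. A difference between 2 single cultures, such as in density or medium, cannot be told apart from an effect of HADH-S with 1 library per condition. Nor can a response to the introduced construct, for the reason given for the interferon-stimulated genes.

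Fold changes depended weakly on transcript length, with Spearman's rho of -0.19 across genes, which are not independent, and with medians of 0.06 in the shortest 10% of transcripts (up to 1237 nt) and -0.06 in the longest (from 7131 nt). This trend may account for part of the lower invasion and matrix list, which moved to percentile 11.2 when the trend was removed, while its median moved from -0.100 to -0.067. It was argued against for the G2/M list, which moved to percentile 0.49, and for the p53 targets, which were at percentile 99.4. No biological explanation was tested for these small shifts.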
